A study of Mus musculus with 7 samples.

How the data were processed

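The material was skin from 7 mice, 3 without Tuft1 and 4 wild type, with 1 library per mouse. Per the labels, RNA was extracted from powdered frozen tissue with TRIzol and made into libraries with the QuantSeq kit, which reads a stretch near the 3' end of polyadenylated transcripts. The number of counts therefore does not grow with transcript length. Groups came from the genotype in the labels. Mouse numbers are not shared between the groups, so no samples were paired and no block was fitted.

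The deposited raw table holds whole-number counts per gene for 56691 genes, with the exon coordinates of each gene, and the authors made it from aligned reads. The submitters' processing notes name STAR, GATK 4.2.4.0, featureCounts, Subread 2.0.3 and edgeR 3.36.0 and the mm39 genome build, without saying in which order or for which step each tool was used. Whether strand was used in counting, and whether duplicate reads were removed, is not given in the sources used here. A second deposited table holds log2 values that the authors filtered and normalized, for 12954 genes. All 90678 of its values were recovered from the raw counts of those genes as edgeR log2 CPM with TMM factors and a prior count of 2, within a tolerance of 1e-09. That table was used only for this check and to define an alternative set of genes. Coordinates were taken from the raw table, since the reference genome at hand is another build, and no check of GC content was made.

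The comparison used the raw counts of all 7 libraries in edgeR 4.0.16 under R 4.3.3. Genes with too few counts for either group were removed with edgeR's expression filter at its default minimum of 10 counts, which left 12888 of the 19128 genes with any count. Libraries were scaled with TMM factors, and the groups were compared with the quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Log2 fold changes are knockout over wild type, each with a standard error derived from the F statistic. Levels are TMM-scaled CPM (counts divided by the scaled library size), as mean ± SD over mice. Single values were compared with an exact two-sided permutation test over the 35 splits of 7 mice into 3 and 4, whose smallest possible p is 0.0286.

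Before the data were examined, 42 lists of genes were fixed for skin cell types, epidermal and hair structures, tissues that a piece of skin can carry, stress and metabolism, and sex. The 907 listed genes included 656 that were tested. The 41 lists with at least 3 tested genes were compared with all other genes by camera in limma 3.58.1, with a preset correlation between genes of 0.01 and adjustment over the lists. The same test with an estimated correlation, and fry, stood beside it. Members were also adjusted over the list alone. A list's score in a library is the mean log2 CPM of its tested members. The mammary epithelium list had 1 tested gene, Prlr, at a log2 fold change of 1.09 (SE 0.66), and was not tested.

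Named genes followed a rule fixed at the same time. It took Tuft1, and in each direction the 12 called genes with the largest changes, an average log2 CPM of at least 1 and no overlap between the groups, or all where fewer passed. Predicted gene models and pseudogenes were counted but not named. From each list it took up to 4 called members, or, where none was called, up to 2 members with the smallest p, given as values. The sex-linked list was taken in every library. Not every gene that the rule allows is printed, 1 gene called under an added filter is not reported here, and genes printed outside it are marked as chosen after their values were seen. Exons of 18 of the 82 genes under the rule overlap exons of another gene, and for 11 of these the other gene had counts. These values, and those of near-identical copies, are uncertain.

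The procedure was tested on simulated data drawn from the real means and library sizes, with 200 genes and 1 list changed. The changed list passed camera at p under 0.05, as did 2 of 40 unchanged lists. The simulated genes were drawn independently, so this does not test camera on lists whose genes vary together. In the real data the estimated correlation was 0.318 for the fat cell list and 0.435 for the immediate early list, against the preset 0.01. For the comparison of knockout and wild type over 12888 genes, 4% of genes changed 2-fold were called, 20% of those changed 4-fold, 32% of those changed 8-fold and 48% of those changed 16-fold. Of 12668 unchanged genes, 4 were called. The common biological coefficient of variation in the real data was 108%. Counts of 0 allow a level of up to 0.323 to 0.395 TMM-scaled CPM by library, taking 3 counts as the limit, and 0.373 on average over the knockout libraries. This limit covers counting error only, because reads without molecular tags are not independent molecules.

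Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, TMM factors from genes outside the hair, muscle and fat lists, library totals, no filter, at least 5 CPM in 3 libraries, the genes of the authors' normalized table, the DESeq2 Wald test, limma-voom with and without sample weights, edgeR's likelihood ratio test, a robust fit, thresholds of 0.1 and 0.01, and leaving out each mouse. Alternatives chosen after seeing the data were edgeR's exact test, the removal of mitochondrially encoded genes, and a grid of 14 filters on abundance of which 1 had been fixed earlier. All 35 splits of the mice were refitted.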

Results

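Transcripts were counted in skin of 7 mice with libraries that read the 3' ends of polyadenylated RNA. Skin of healthy appearance came from 3 mice lacking Tuft1 (mice 2, 3 and 4), and skin of 4 wild-type mice (mice 5, 6, 7 and 8) served as the control. Knockout libraries 2, 3 and 4 held 7846643, 9086523 and 7009237 counts, and wild-type libraries 5, 6, 7 and 8 held 9256459, 8612027, 8768984 and 8490972 counts (exact two-sided permutation p = 0.2 between groups). Between 12302 and 14379 genes had counts in a library, and mitochondrially encoded transcripts took 12.3% to 21.6% of the counts. Expression profiles correlated across genes with Pearson's r of 0.607 to 0.726 in the 21 pairs of libraries, with a mean of 0.661 within and 0.652 between groups. Genes are not independent replicates for this correlation. Of 12226 genes reaching 100 counts in some library, 4036 had 0 counts in another.

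Sex-linked genes were alike in kind in both groups. Xist had 0 counts in all 7 libraries. Ddx3y had 635, 835 and 1001 counts in knockout mice 2, 3 and 4, and 1166, 661, 1119 and 1079 counts in wild-type mice 5, 6, 7 and 8. In the same order, Eif2s3y had 146, 120 and 200 counts against 480, 562, 205 and 331 counts, and Uty had 163, 588 and 69 counts against 203, 82, 57 and 150 counts. Kdm5d had 7, 195 and 39 counts against 93, 91, 84 and 49 counts.

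The comparison asked which transcripts differ in skin without tuftelin 1, a protein that the study links to desmosomes, the junctions that hold keratinocytes together. Tuft1 transcripts (ENSMUSG00000005968.15) were at 22.1 ± 6.23 CPM (SD, n = 3) in knockout and 94.9 ± 26.6 CPM (SD, n = 4) in wild-type skin, or 23.3% of the wild-type level. Knockout skin held more Krt6a, a keratin of stressed and follicular epithelium, and more Defb8, a beta-defensin, and less Npr3, the clearance receptor of natriuretic peptides. These were the only 3 of 12888 genes called by edgeR's quasi-likelihood test, 2 higher and 1 lower. As a group, fat cell genes were lower in knockout skin by a median log2 fold change of -1.04 in the set test, a call not held with an estimated correlation (adjusted p = 0.217), and 0 of these genes were called over all genes.

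In single libraries, Tuft1 stood at 19.9, 29.1 and 17.2 CPM in knockout mice 2, 3 and 4, and at 106, 104, 55.6 and 114 CPM in wild-type mice 5, 6, 7 and 8. The log2 fold change was -2.10 (SE 0.39), with an adjusted p = 0.172 by edgeR's quasi-likelihood test, so Tuft1 itself was not called, and ranked 10 by p. An exact two-sided permutation test of its levels gave p = 0.0286, the smallest that 35 splits allow. The gene lies on the minus strand of chromosome 3 at 94520064 to 94566179 (mm39). The labels do not say which part of it was deleted, and tags outside the deleted part would still be counted, so the remaining counts check the labels only in part.

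**Figure D1:**
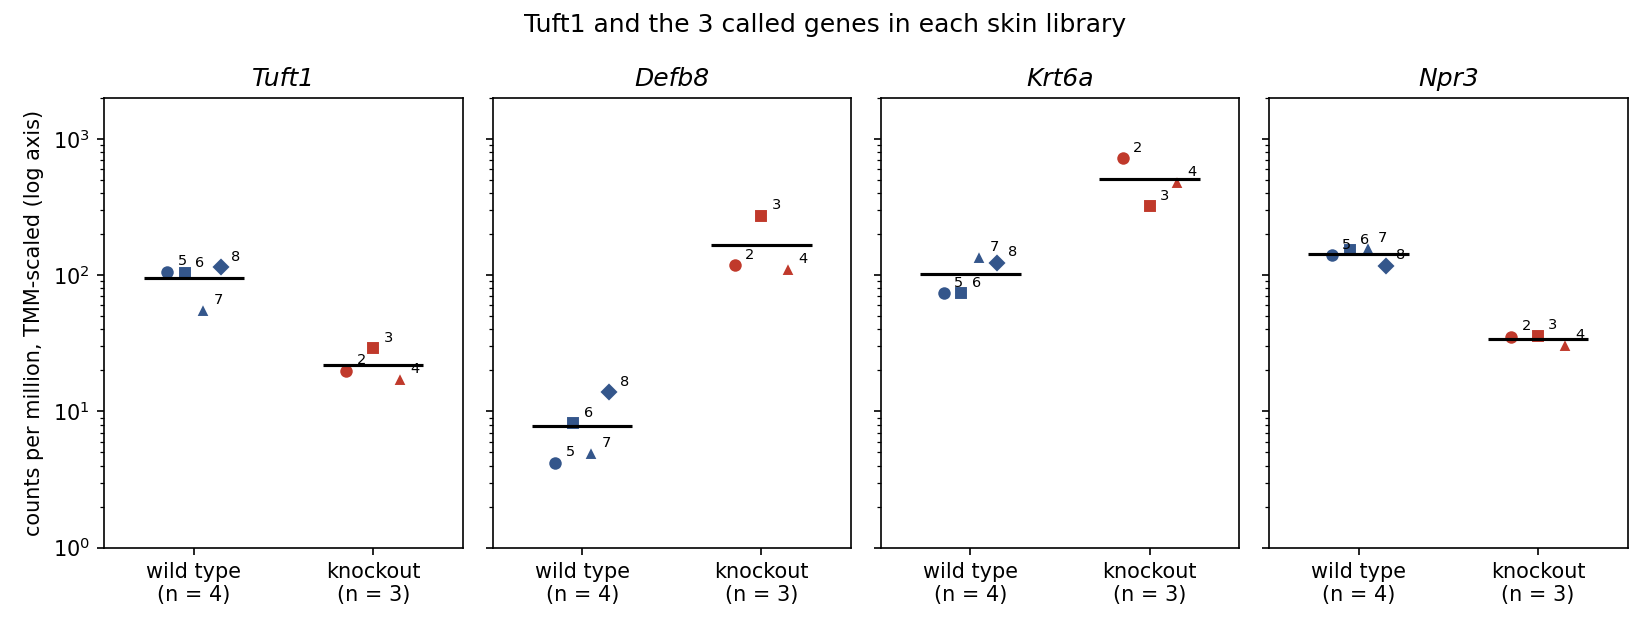
Levels of Tuft1, Defb8, Krt6a and Npr3 in TMM-scaled CPM on a log axis, with 1 point per mouse labelled by its number and a bar at the group mean. In each of the 4 genes the 3 knockout mice lie on one side of the 4 wild-type mice, and Tuft1 stands at 17.2 to 29.1 CPM in knockout skin.

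Defb8 (ENSMUSG00000031471.4, chromosome 8, 19495785 to 19497622, mm39) was at 168 ± 92.0 CPM (SD, n = 3) in knockout and 7.80 ± 4.41 CPM (SD, n = 4) in wild-type skin, with a log2 fold change of 4.43 (SE 0.50, edgeR adjusted p = 0.00911). Krt6a (ENSMUSG00000058354.8, chromosome 15, 101598345 to 101602742) was at 508 ± 201 CPM in knockout and 102 ± 32.2 CPM in wild-type skin, with a log2 fold change of 2.32 (SE 0.31, edgeR adjusted p = 0.0256). Npr3 (ENSMUSG00000022206.8, chromosome 15, 11839982 to 11907373) was at 34.0 ± 2.94 CPM in knockout and 142 ± 18.1 CPM in wild-type skin, with a log2 fold change of -2.06 (SE 0.28, edgeR adjusted p = 0.0256). All 3 genes were separated without overlap between the groups, as were 888 of the 12888 genes tested (6.89%, against 5.71% by chance). Defb8 and Krt6a belong to families with closely similar copies, so the assignment of their reads is uncertain, and Npr3 overlaps an antisense gene that held 28 counts beside its own 5723. Leaving out any of the 7 mice ended the calls of Krt6a and Npr3, and leaving out knockout mouse 3 or wild-type mouse 5, 6 or 7 ended that of Defb8 (adjusted p from 0.0579 to 0.246 for Krt6a, 0.0635 to 0.200 for Npr3 and 0.0145 to 0.101 for Defb8 with edgeR). In edgeR 555 genes had an unadjusted p under 0.05, below the 644 that make 5% of the genes tested. The other splits of the mice gave 241 to 596 such genes, so 644 is not the number that chance gives in these data. The 4 fits with 1 mouse left out that called 0 genes had 464 to 522. Other settings called up to 101 genes (the DESeq2 Wald test), with 22 in limma-voom and 76 without a filter on low counts. Among the 3473 genes at a mean of at least 50 CPM, a filter chosen after seeing the data from 14 that gave 2 to 27 calls, 24 genes were called, Tuft1 among them (adjusted p = 0.0250, within 1.32e-05 to 0.712 over its alternatives).

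Of 20 tested fat cell genes, 19 had a log2 fold change below 0, and the list passed the set test (camera adjusted p = 1.33e-25). With an estimated correlation the list was not called (adjusted p = 0.217), nor with fry (adjusted p = 0.140). None was called over all genes, and 12 were lower when adjusted over the list alone. Adipoq, which encodes the fat cell hormone adiponectin, was at 300.4 ± 53.8 CPM in knockout and 833 ± 194 CPM in wild-type skin (log2 fold change -1.47, SE 0.24). Lpl, which encodes lipoprotein lipase, was at 1179 ± 143 CPM and 3154 ± 878 CPM (log2 fold change -1.42, SE 0.24). The list's mean log2 CPM was 7.10 ± 0.48 (SD, n = 3) in knockout and 8.27 ± 0.29 (SD, n = 4) in wild-type skin, and each of the 3 knockout mice lay below the 4 wild-type mice. The exact permutation p of this score was 0.0286, the smallest possible, and 0.586 when adjusted over the 41 tested lists. The split that set wild-type mice 5, 6 and 8 against the other 4 mice gave a list median of 1.11, larger in size than that of the genotypes, with a camera p of 4.81e-26 against 3.25e-27. Those other 4 were the 3 knockout mice and wild-type mouse 7. A difference between the genotypes would therefore show in that split too, and it is no independent rival to the genotypes. The list took 1.05% of the counts in knockout and 2.06% in wild-type skin.

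**Figure D2:**
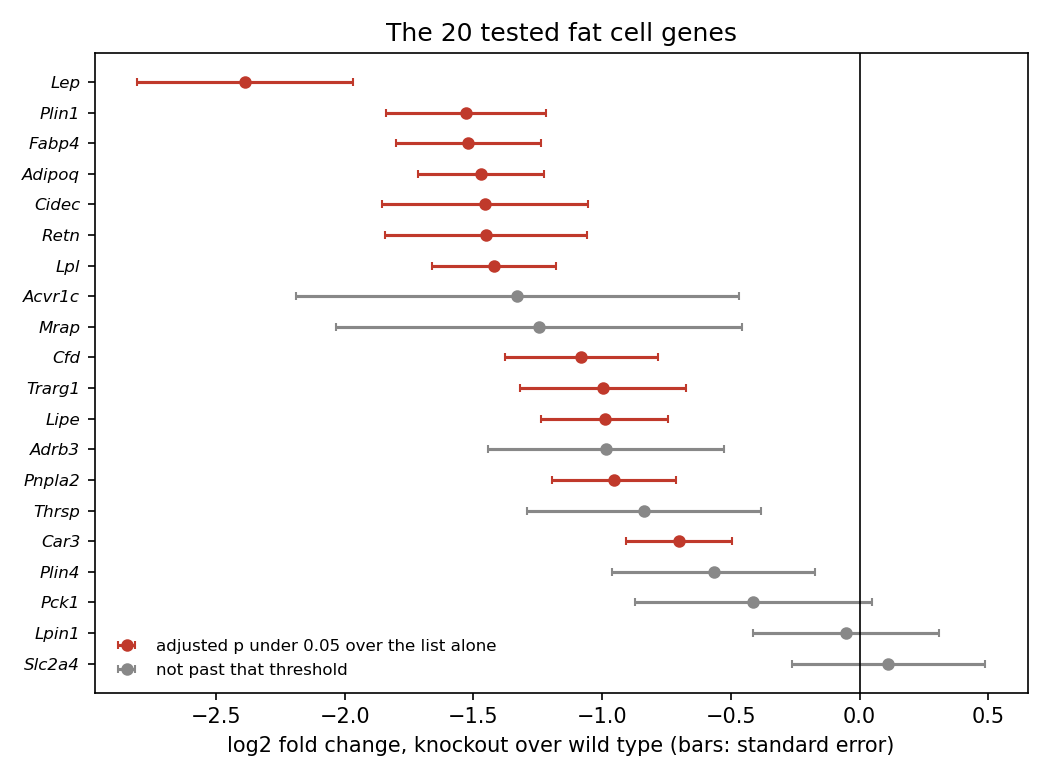
Log2 fold changes of the 20 tested fat cell genes, knockout over wild type, with bars of 1 standard error; red points had an adjusted p under 0.05 over the list alone. Of these genes 19 lie below 0, from Lep at -2.39 to Lpin1 at -0.05, and Slc2a4 lies at 0.11 (these 3 were named after their values were seen).

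In all, 7 of 41 lists passed the set test, 0 of them with an estimated correlation or with fry (4 and 5 lists at unadjusted p under 0.05), and 10 of the 35 splits of the mice gave as many. Genes of hair follicle stem cells were higher in knockout skin, with 12 of 12 tested members above 0 and a median log2 fold change of 0.69 (camera adjusted p = 5.11e-06, and adjusted p = 0.217 with an estimated correlation). When adjusted over the list alone, 2 members were higher and 0 lower. Lhx2, a transcription factor of the follicle, was at 141 ± 61.1 CPM in knockout and 31.1 ± 15.8 CPM in wild-type skin, and Sox9 was at 500.2 ± 209 CPM and 214 ± 67.3 CPM. Sebaceous gland genes had 13 of 18 members above 0 and a median of 0.58 (camera adjusted p = 0.0231, and adjusted p = 0.597 with an estimated correlation), with 5 higher and 2 lower when adjusted over the list alone. Krt79 was at 269 ± 43.9 CPM in knockout and 120.3 ± 31.9 CPM in wild-type skin. The 2 lower members, Dgat2 and Pparg (Pparg named after its values were seen), serve triglyceride storage in fat cells as well, and Dgat2 was at 380 ± 73.2 CPM in knockout and 1063 ± 240 CPM in wild-type skin. Without knockout mouse 3 or 4, or wild-type mouse 6 or 7, the sebaceous list was not called (camera adjusted p = 0.346, 0.0904, 0.0701 and 0.115).

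Melanocyte genes had 7 of 7 tested members above 0, with a median of 0.77 (camera adjusted p = 0.0102, and adjusted p = 0.418 with an estimated correlation), and 0 were called when adjusted over the list alone. Sox10 was at 20.7 ± 10.6 CPM in knockout and 5.16 ± 4.46 CPM in wild-type skin, and Gpnmb at 231 ± 94.1 CPM and 144 ± 43.9 CPM. The call ended without knockout mouse 2 (median 0.43, camera adjusted p = 0.124) or wild-type mouse 7 (median 0.67, camera adjusted p = 0.0504), and the median was 1.21 without wild-type mouse 6 and 1.23 without wild-type mouse 8. Skeletal muscle genes had 22 of 23 members above 0, with a smaller median of 0.32 (camera adjusted p = 0.00212, and adjusted p = 0.597 with an estimated correlation), and 0 were called when adjusted over the list alone. Myh4, a myosin of fast muscle fibres, was at 3556 ± 2923 CPM in knockout and 1363 ± 493 CPM in wild-type skin. It stood at 540, 6376 and 3753 CPM in knockout mice 2, 3 and 4, and mouse 2 lay below the wild-type range of 756 to 1825 CPM.

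Immediate early genes, which respond within minutes to stimulation and to tissue handling, had 20 of 20 members below 0 and a median of -0.97 (camera adjusted p = 4.90e-13, and adjusted p = 0.418 with an estimated correlation). Adjusted over the list alone, 9 were lower, and 0 over all genes. Btg2 was at 47.6 ± 4.32 CPM in knockout and 190.4 ± 98.6 CPM in wild-type skin, and Egr1 at 308 ± 7.66 CPM and 685 ± 247 CPM. The list's mean log2 CPM was 6.06 in wild-type mouse 8, inside the knockout range of 5.89 to 6.22, while the other wild-type mice were at 7.03 to 7.72 (exact permutation p = 0.114 between groups). Erythrocyte genes, a sign of blood in the tissue, had 5 of 5 members below 0 and a median of -1.11 (camera adjusted p = 0.00393, and adjusted p = 0.597 with an estimated correlation), and 0 were called when adjusted over the list alone. Hbb-bs was at 312 ± 165 CPM in knockout and 672 ± 298 CPM in wild-type skin, and is uncertain because globin copies are nearly identical. The erythrocyte call ended without knockout mouse 3 (camera adjusted p = 0.0804) or wild-type mouse 8 (camera adjusted p = 0.0552).

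**Figure D3:**
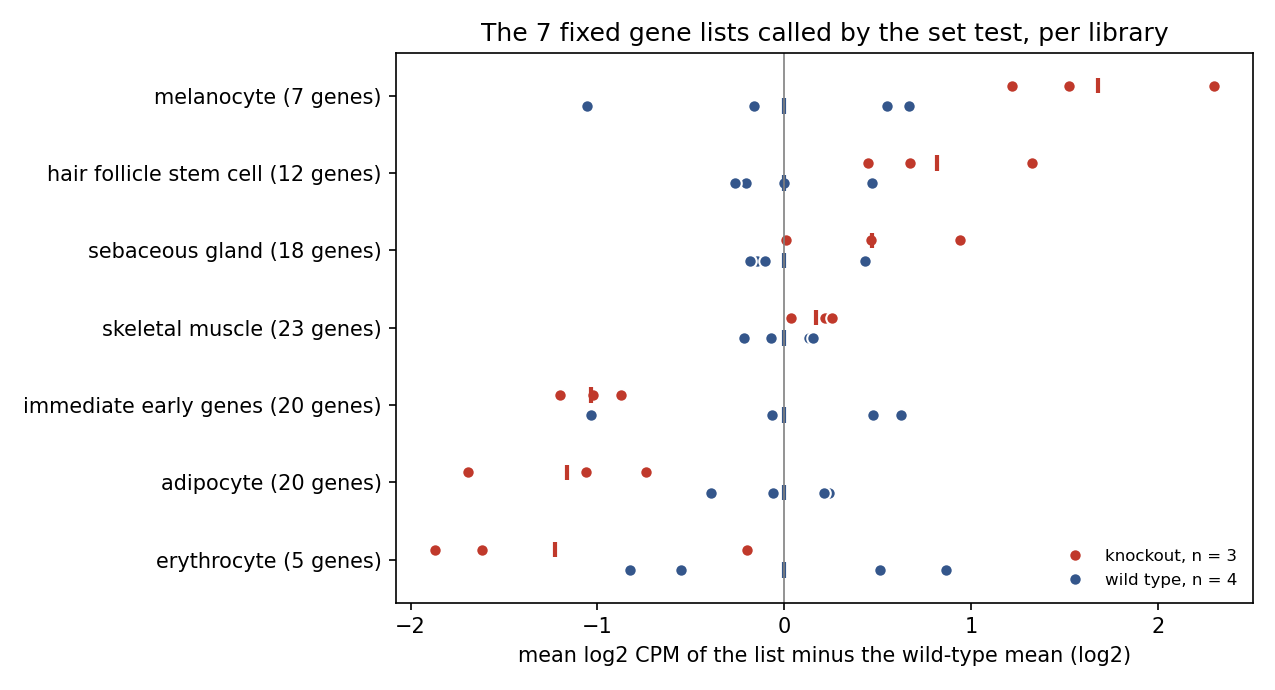
Mean log2 CPM of the 7 lists that passed the set test in each library, minus the wild-type mean; red points are the 3 knockout and blue points the 4 wild-type mice, and vertical ticks are group means. The groups are apart without overlap in the melanocyte and adipocyte lists, and overlap in the other 5. Adjusted over the 41 tested lists, the exact permutation p of the melanocyte and adipocyte scores is 0.586 for each.

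Desmosome genes were not called as a list, with a median log2 fold change of -0.26 over 15 members (camera adjusted p = 0.251). Ppl, which encodes the cornified envelope and desmosome protein periplakin, was at 266 ± 94.5 CPM in knockout and 422 ± 44.2 CPM in wild-type skin (edgeR adjusted p = 1.00). The other lists of epidermal structure did not pass the set test either. Medians and camera adjusted p were 0.03 and 0.823 for adherens and tight junctions, 0.05 and 0.393 for hemidesmosomes and basement membrane, 0.14 and 0.481 for basal keratinocytes, and -0.16 and 0.118 for suprabasal keratinocytes and the cornified envelope. The suprabasal median was -0.38 without knockout mouse 2, and the list was then called (camera adjusted p = 0.00683, within 0.00411 to 0.597 over its alternatives). Medians and adjusted p were -0.04 and 0.431 for partners of the keratin network, 0.01 and 0.287 for the epidermal lipid barrier, and -0.17 and 0.337 for stress keratins and alarmins, the list that holds Krt6a. Adjusted over the list alone, Flg was higher and Lce1m lower among suprabasal genes, and Slc27a4 and Fa2h, proteins of skin lipid metabolism, were higher among barrier genes. Among stress genes Krt6a was higher and Areg lower, with Areg (named after its values were seen) at 0 counts in the 3 knockout libraries and in at least 1 wild-type library. At a mean of at least 50 CPM, the filter chosen after seeing the data, 3 of the 16 stress genes were left, Krt6a among them, and these were called as a list (median 1.45, camera adjusted p = 1.20e-06, within 1.20e-06 to 0.866 over its alternatives, which include an adjusted p = 0.597 with an estimated correlation). Over all 16 members 8 lay above 0 and 8 below. Fa2h was at 485 ± 174 CPM in knockout and 194 ± 70.4 CPM in wild-type skin.

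Lists of hair structure were not called. Medians and camera adjusted p were 0.12 and 0.393 for hair and inner root sheath keratins, -0.31 and 0.565 for keratin-associated proteins, 0.51 and 0.188 for hair shaft regulators, -0.12 and 0.461 for genes of wavy and curly coats, and 0.10 and 0.270 for hair growth signals. Only 4 members of the hair keratin list and 3 keratin-associated proteins had enough counts to be tested. The 4 include Krt79 and Krt80, which are left out where hair genes are counted below, so the median of 0.12 describes hair keratins only in part. Knockout mouse 2 stood apart in these genes: 39 of 47 keratin-associated protein genes in the table had counts there, against 2 to 3 in each of the other 6 libraries. Without this mouse Krt6a had a log2 fold change of 1.98 (edgeR adjusted p = 0.0929), and the follicle stem cell and fat lists were called at medians of 0.75 and -1.24 with the preset correlation (adjusted p = 0.217 for each over all 7 mice with an estimated correlation).

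Among other cell types, medians and camera adjusted p were 0.33 and 0.113 for fibroblasts and dermal matrix, -0.69 and 0.119 for endothelium, -0.32 and 0.241 for smooth muscle and pericytes, 0.01 and 0.355 for Schwann cells, 0.48 and 0.152 for mast cells and 0.28 and 0.222 for macrophages. They were -0.05 and 0.637 for Langerhans and dendritic cells, 0.48 and 0.249 for T cells, 1.34 and 0.208 for B and plasma cells and -0.35 and 0.953 for neutrophils. Tek, an endothelial receptor, had 0 counts in the 3 knockout libraries and was at 6.86 ± 3.15 CPM in wild-type skin. Tek was not called (edgeR adjusted p = 0.9997) and is named as the member with the smallest p. Taking 3 counts per library as the limit, it was at least 18.4-fold lower if counting error were the only error. Of 12226 genes reaching 100 counts in some library, 4036 had 0 in another, so zeros alone are weak evidence of a fall. The endothelial median is -0.69 also with genes at 0 counts in a group set at their limits. With 1 mouse left out that median ran from -0.78 without knockout mouse 3 to -0.29 without knockout mouse 4. For stress and metabolism, the values were -0.11 and 0.270 for inflammatory cytokines, 0.41 and 0.188 for interferon response, -0.17 and 0.656 for the cell cycle, -0.12 and 0.962 for actin and adhesion signalling, -0.25 and 0.393 for heat shock, and 0.12 and 0.241 for the circadian clock. They were 0.08 and 0.165 for cholesterol synthesis, -0.08 and 0.962 for fatty acid oxidation, -0.02 and 0.957 for oxidative phosphorylation, -0.10 and 0.119 for the cytosolic ribosome and -0.09 and 0.522 for sex-linked genes. In 10 of the 34 uncalled lists the median or the mean differed in sign from the test: circadian clock, stress keratins, hemidesmosomes, keratin-associated proteins, Langerhans cells, cell cycle, adherens junctions, neutrophils, actin and fatty acid oxidation.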

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

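The tests on uneven counts and on unadjusted p near Tuft1 were chosen only after the result was seen; the test of called genes near Tuft1 was chosen before. Of 127 groups of 4 wild-type values, 6 held a mouse far from the other 3, where chance gives about 1 in 20 (6.35), so these may all be chance. Tuft1 was at a log2 CPM of 5.80 in wild-type mouse 7, against 6.70 to 6.84 in the others. Tek was at 1.30 in wild-type mouse 8, against 2.96 to 3.20. Tpsb2 was at 7.08 in wild-type mouse 5, against 7.46 to 7.52. Ddx3y was at 6.22 in wild-type mouse 6, against 6.97 to 7.10. Kdm5d was at 2.66 in wild-type mouse 8, the other 3 reaching up to 3.40. The mean log2 CPM of the sebaceous gland list was 6.33 in wild-type mouse 8, against 5.72 to 5.80. The knockout group of 3 was not tested in this way.

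Of 12226 genes with at least 100 counts in some library, 4036 (33.0%) had 0 counts in another. Too few reads per library is argued against: where the other libraries led to at least 50 counts being expected, at least 237 genes per library (237 to 1040) had 0, and Poisson sampling gives fewer than 1. A difference between the genotypes as the main source is argued against too: of 619 genes at 0 in exactly 3 libraries, the 3 were the knockouts for 18 (2.91%, 95% exact interval 1.73 to 4.56). Chance gives 2.86% if all libraries lose genes alike, which they did not. Of genes expected at 50 or more counts, 2.25% were at 0 in knockout mouse 2, against 9.47% and 8.17% in knockout mice 3 and 4. Wild-type libraries ran from 3.26% to 8.75%. The share that chance gives for the knockouts may thus be lower, and a smaller excess is not excluded. Few starting molecules, each read many times, is a candidate explanation that stays open: genes with at least 10 counts in 1 library and under 10 in each of the others had a median of 35 counts in knockout mouse 2 and 37 to 62.5 in the other 6 libraries, and the bound set for this explanation was at least 50 in each. No table here counts molecules.

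Tuft1 lies beside the epidermal differentiation genes on chromosome 3, and alleles of the strain in which it was targeted could travel with it. Of 258 tested genes within 10 Mb, 0 were called with edgeR, against 3 of 12629 elsewhere (Fisher exact two-sided p = 1), too few calls to decide. At an unadjusted p under 0.05 there were 13 of 258 (5.04%) against 541 of 12629 (4.28%), with an odds ratio of 1.19 (95% interval 0.618 to 2.08, Fisher exact two-sided p = 0.533). Flanking alleles and an effect of Tuft1 on nearby genes cannot be told apart, since that interval spans 1 and the 13 include skin genes such as S100a4 (named after its values were seen), Flg and Lce1m.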

How the results depend on the processing

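The exact test of edgeR, the removal of mitochondrial genes and all abundance filters but 5 CPM in 3 libraries were chosen only after the result was seen. With a biological coefficient of variation of 108%, the test on simulated data recovered 48% of 16-fold changes, and 15 of 16 above 50 CPM. Defb8, Krt6a, Npr3 and Tuft1 kept their direction in all 22 alternatives. Over the named genes, 1674 values kept direction and side of the threshold, 72 gained a call, 20 lost it and 4 reversed; for lists these were 724, 29, 25 and 32. Scaling by DESeq2 size factors, library totals or TMM outside the hair, muscle and fat lists, at least 5 CPM in 3 libraries, the authors' genes and the removal of mitochondrial genes each called 3 genes, the same 3. A sex covariate was not run, since the sex-linked genes were alike in kind in all 7 libraries.

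The 3 called genes became 76 with no low-count filter, 22 with limma-voom, 17 with sample weights, 27 with the likelihood ratio test, 9 with the robust fit, 101 with the DESeq2 Wald test, 6 at an adjusted p under 0.1 and 1 under 0.01. The alternatives chosen after seeing the data gave 20 with edgeR's exact test, 10, 2, 7, 24 and 24 at a mean of at least 1, 10, 20, 50 and 100 CPM, and 7, 21 and 27 at 20, 50 and 100 CPM in 3 libraries. The 3 genes were among the calls under each of these filters and tests apart from both voom fits, which shared 2, without Defb8, an adjusted p under 0.01, with 1 call, and means of 10 and 100 CPM, which shared 2 and 1. Fewer genes tested can raise calls by a lighter adjustment, but that was not the only change. The common biological coefficient of variation was 108% in the main fit, 49.6% at a mean of 20 CPM and 33.6% at a mean of 50 CPM. A mean of at least 1 CPM tested more genes than the main fit (15074) and still called 10. How much each change adds was not tested. With 1 mouse left out, 0 to 1 genes were called. Tuft1 was called at -2.11 with no filter, -2.10 by the likelihood ratio and exact tests, -2.08 by DESeq2 and -2.08 at a mean of 50 CPM (adjusted p 1.32e-05 to 0.712 over all alternatives).

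The 7 lists became 0 with an estimated correlation in camera, 0 with fry (4 and 5 at unadjusted p under 0.05), 13 with no filter (among them the mammary epithelium list, otherwise too small to test) and 6 to 11 with 1 mouse left out. The melanocyte median of 0.77 reached 2.29 with limma-voom. The sebaceous list was also lost at 5 CPM in 3 libraries (0.0691), with voom weights (0.104) and at a mean of 50 CPM (0.181). With no filter the hair keratin and keratin-associated protein lists were called at medians of 7.27 and 8.18, on counts mostly from knockout mouse 2. Other uncalled lists gained a call with no filter (suprabasal, adjusted p = 0.0430; hair shaft, 0.0258; B cell, 0.00286), with voom (suprabasal, 0.00411; ribosome, 0.0184), with its weights (ribosome, 0.0335; fibroblast, 0.0317), at a mean of 20 CPM (mast cell, 0.00358) and at a mean of 50 CPM (suprabasal, 0.0265; mast cell, 0.00553; stress keratins, 1.20e-06, on 3 of 16 members, Krt6a among them, with a median of 1.45). Uncalled lists also gained a call without knockout mouse 2 (suprabasal, adjusted p = 0.00683; cholesterol, 0.00281), 3 (hair shaft, 0.0120; fibroblast, 0.0120; endothelial, 0.0402) or 4 (fibroblast, 0.00231; macrophage, 0.0345; ribosome, 0.0434), and without wild-type mouse 6 (suprabasal, B cell and interferon, each 0.0347; fibroblast, 0.0209; macrophage, 0.0390), 7 (endothelial, 0.0125) or 8 (fibroblast, 0.0243; ribosome, 0.00990).

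Reversed values were not called on either side, and the cause was not tested. Kdm5d was -0.83 with voom, -1.32 with weights and -1.60 to 0.56 with 1 mouse left out. For lists the direction of the set test turned, at medians, for actin, of -0.12 (fry), -0.15 (voom), -0.15 (mean of 20 CPM), -0.14 (no filter) and -0.15 to -0.020 with 1 mouse left out; for fatty acid oxidation, -0.083 (fry), -0.0713 and -0.0646 (means of 20 and 50 CPM), -0.087 (no filter) and -0.19 to 0.12; for oxidative phosphorylation, -0.012 (DESeq2 factors), 0.030 (totals), -0.00784 (voom weights), 0.0045 (mean of 50 CPM) and -0.0554 to 0.0414. Wavy coat genes were at 0.023 with no filter and interferon at -0.31 at a mean of 50 CPM. With 1 mouse left out the medians ran from -0.17 to 0.12 (Langerhans), -0.19 to 0.27 (Schwann), -0.15 to 0.10 (adherens), -0.23 to 0.24 (cell cycle), -0.13 to 0.62 (fibroblast), -0.13 to 0.62 (macrophage), -0.42 to 0.023 (neutrophil) and -0.57 to 0.24 (sex-linked). For other lists they ran from 0.93 to 2.38 (B cell), 0.20 to 0.60 (T cell), 0.49 to 0.65 (mast cell), -0.016 to 0.83 (interferon), -0.47 to -0.090 (cytokines), -0.38 to -0.046 (suprabasal), -0.42 to 0.42 (stress keratins), -0.013 to 0.20 (basal), -0.12 to 0.13 (hemidesmosome), -0.36 to -0.17 (desmosome), -0.29 to -0.035 (keratin partners), -0.10 to 0.18 (lipid barrier), -0.18 to 0.50 (hair keratins), -0.67 to 0.47 (keratin-associated proteins), 0.33 to 0.83 (hair shaft), 0.065 to 0.40 (hair growth), -0.32 to 0.021 (wavy coat), -0.53 to -0.041 (smooth muscle), -0.28 to -0.071 (heat shock), 0.025 to 0.39 (circadian), -0.13 to 0.25 (cholesterol) and -0.18 to -0.038 (ribosome).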

Other observations

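The tests in this part were chosen only after the result was seen, apart from the count of splits for all tested genes, and so were the genes named here; the permutation tests on fat genes replaced Cochran's Q, which had come out on the same sides of 0.05. Among the 3473 genes at a mean of at least 50 CPM, edgeR called 9 genes higher and 15 lower in knockout skin. This filter was taken from 14 filters on abundance, of which 1 was listed before the data were examined, and they gave 2 to 27 calls. Beside Adipoq, Lep, Plin1, Lpl and Fabp4, the lower genes held Cd36, a fatty acid receptor, at a log2 fold change of -1.37 (SE 0.23), Hp, which encodes haptoglobin, at -1.91 (SE 0.34) and Plaat3, a phospholipase of fat tissue, at -1.26 (SE 0.26). Rgs2 was at -1.46 (SE 0.33) and Slc1a5, a glutamine transporter, at -1.22 (SE 0.26). Higher genes included Slc27a4 at 1.84 (SE 0.37), Cers4, a ceramide synthase, at 1.79 (SE 0.37), Fa2h at 1.37 (SE 0.30), the retinol dehydrogenase gene Sdr16c5 at 1.84 (SE 0.38) and S100a4 at 1.10 (SE 0.21). Tuft1 was at -2.08 (SE 0.42).

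Hair keratins and keratin-associated proteins were counted mostly in 1 library. Of 84 genes of the 3 hair lists with counts (Krt79 and Krt80 left out), 68 had their highest level in knockout mouse 2 and 53 had counts only there. Hair and inner root sheath keratins had counts for 21 of 24 genes in that library and for 2 to 4 in each of the other 6, with summed levels of 737 CPM against 53.1 to 166 CPM. Keratin-associated proteins had counts for 39 of 47 genes there and for 2 to 3 elsewhere, with 895 CPM against 34.0 to 83.8 CPM. Hair shaft regulators and other hair proteins stood apart less, and hardly in their summed level. They had counts for 23 of 29 genes in knockout mouse 2 and for 12 to 17 elsewhere, with 1652 CPM against 1043 to 1615 CPM. A sum mostly follows the abundant members. The mean log2 CPM of the tested members was 5.11 in knockout mouse 2 and 2.17 to 3.77 in the other 6 libraries. Whether that piece of skin held growing hair was not tested.

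Splits of the 7 mice into 3 and 4 gave 35 groupings. The 3 called genes were matched in 1 of 35, the real one, with 1 call at most in the others. Chance is argued against for this count, at the smallest share that the design allows. It is not strictly excluded, since the count is small and 0 to 1 genes were called with 1 mouse left out. Nor is chance excluded for genes at an unadjusted p under 0.05, which numbered 555 in the real split and 596 and 581 in 2 others. For the 24 genes at a mean of at least 50 CPM the count was 1 of 35, with at most 6 in the others, but that filter was chosen on the real grouping, so this says nothing about chance. Taking each split at the filter among the 14 that gave it the most calls, the real split had 27 and the others at most 12 (1 of 35, again the smallest share possible). All but 1 of the 14 filters were chosen after the real grouping was seen, so no conclusion about chance is drawn from that count. Chance cannot be excluded for the number of lists, since 10 of 35 splits, the real one among them, called at least 7, and the highest count was 11.

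Fat cell genes were lower beside higher follicle genes in the set test, and neither call held with an estimated correlation (adjusted p = 0.217 for each). Transcripts of the listed fat genes taking up counts in wild-type libraries is argued against, since their shares would raise all other genes by a log2 of 0.015, and the follicle stem cell score differed by 0.82 (SE 0.31). The rise in that score is itself uncertain, with an exact permutation p of 0.0857, and 0.750 when adjusted over the 41 tested lists. The skeletal muscle median of 0.32 showed no loss of muscle from the knockout pieces. The muscle score was 0.17 higher in knockout skin, a difference not detected with 3 and 4 mice (exact permutation p = 0.2) and not excluded either. A cut that loses fat but keeps muscle was not tested, so a shallower sample stays open. Less fat tissue in the knockout pieces may account for Adipoq, Lep, Plin1, Cidec, Retn and Cfd, which are largely restricted to fat cells. Their mean log2 fold change, with each gene weighted by the inverse square of its standard error, was -1.49 (SE 0.13, taking genes as independent). They showed no detected departure from a common fold (exact permutation p = 0.371). Over all 20 fat genes the folds differed (exact permutation p = 0.0286, the smallest possible), but muscle also expresses some, such as Car3 and Slc2a4, so for the whole list less fat tissue cannot be told apart from lower expression within fat cells.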
